A study of Mus musculus with 32 samples.

How the data were processed

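Polyadenylated RNA of the dorsal hippocampus was sequenced in 32 mice, 4 in each of 8 groups of sex, prenatal treatment and lighting, per the labels. The authors deposited 2 tables of read counts per gene, 1 for each sex, and 12 tables of log2 fold changes with p-values, 6 for each sex. The count tables hold whole numbers in the layout of STAR's gene counts, and the file name calls them stranded. Trimmomatic 0.35, STAR 2.7.1a, RSEM and DESeq2 1.18.1 are named per the submitters' processing notes, with GRCm38 as the genome build. Neither the role of RSEM nor the annotation release is stated there. The deposited log2 fold changes and p-values have DESeq2's column layout per the file headers, with no filter or covariate stated.

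The 4 rows of each count table that name no gene were left out of library sizes and tests. Relative to all reads they held 16.3% to 25.8% of reads without a feature, 9.29% to 11.9% mapping to several places, 1.79% to 2.52% unmapped and 0.723% to 0.812% ambiguous. Of 55401 gene identifiers 55141 were matched to a symbol in GENCODE mouse release 21, and 54349 had the same version there. Where a symbol lay on more than 1 identifier, the one with more reads was used, which left out 107 identifiers. Gene coordinates come from the same release. Levels of Xist and Ddx3y matched the labelled sex in all 32 libraries.

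Library totals over genes ran from 11.4 to 21.6 M reads, with a median of 17.3 in females and 19.2 in males. Between pairs of libraries of a group chi-square per degree of freedom was 3.56 to 121, so no 2 libraries agreed within counting error. The reads carry no molecular identifiers, so counting error alone is a lower bound on their spread.

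Gene tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr on the group, TMM factors and a robust quasi-likelihood fit of all groups of a sex. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Tests covered 17114 genes in females, 17210 in males and 17771 in a fit of both sexes, with a biological coefficient of variation of 0.265, 0.200 and 0.237. The 21 comparisons were 6 pairs of groups and 1 interaction within each sex, 3 comparisons over both sexes and 4 sex differences. Replicate numbers were not used as a block, since no label ties them to a litter or day. Dams were treated and the litters are unknown, so mice may not be independent. Poly(I:C) effects cannot be told from litter effects. Residuals of libraries with the same number had a median correlation of -0.03 in females and 0.005 in males. Of 16 libraries 3 and 6 were closest to one with their number.

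Fixed before the data were examined were the groups, comparisons, tests, 34 gene lists of cell types, regions and pathways, the named-gene rule and the alternative settings. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjusted p over the lists of a comparison, and again with an estimated correlation and with fry. In LL versus LD over both sexes a regrouping of the libraries gave a preset camera p of 5.61e-22, so a preset call alone shows no group effect. The named genes were up to 10 with the largest rise and 10 with the largest fall among those that passed, with a mean of at least 1 CPM and an official name. Where fewer than 4 passed, the 4 of lowest p were added as values that did not pass. Members of a list that passed and the 3 members of lowest p in each list called by camera were added too. For an interaction or sex difference the rule takes the 5 of lowest adjusted p that pass. Log CPM for scores used a prior count of 2. Some named genes are not reported here.

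The alternatives fixed with them were DESeq2 1.42.0, RLE factors, no filter, a stricter filter, 1 surrogate variable from sva 3.50.0, limma with voomWithQualityWeights, a fit of only the 2 groups compared, the replicate block and leaving out each library in turn. Regional scores as covariates and leaving out libraries with a low dentate score were added after the data were seen. On simulated data with known changes of 1.5-fold, 2-fold and 4-fold, a comparison of 2 female groups recovered 17 of 67, 41 of 67 and 62 of 66 genes, and made 6 false calls among 126. In males 29, 50 and 63 were recovered with 3 false calls among 145, and over both sexes 55, 59 and 66 with 14 among 194. Large changes can be missed where libraries of a group differ, as for Ttr below.

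The authors' deposited tables were used as a check, not as a source of the values reported. For the 14159 genes matched in females and 14120 in males, log2 fold changes in the authors' deposited table had a correlation across genes of 0.994 to 1.00 with those computed here. The authors' deposited tables call 1055 genes in males for poly(I:C) under LD, 1680 for poly(I:C) LD against saline LL and 189 for LL in poly(I:C) offspring. In females they call 83 genes for poly(I:C) under LL, 280 for poly(I:C) LD against saline LL and 2 for LL in saline offspring. In the other comparisons they call 1 or 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.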

Results

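Polyadenylated RNA from the dorsal hippocampus of 32 C57BL/6J mice was sequenced. The dams had received poly(I:C), a double-stranded RNA that mimics a viral infection and sets off an immune response, or saline at gestational day 9. From 3 weeks of age the offspring lived for 4 weeks under 12 h of light and 12 h of darkness (LD) or under constant light (LL). The 8 groups of sex, prenatal treatment and lighting held 4 mice each.

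Reads counted in genes, in M, were 20.6, 11.4, 17.8 and 17.3 in the female poly(I:C) LD libraries, replicates 1 to 4 in that order here and below. Female saline LD libraries had 18.5, 18.2, 14.1 and 13.5. Female poly(I:C) LL libraries had 17.2, 17.0, 17.6 and 21.1, and female saline LL libraries 20.2, 15.8, 16.3 and 17.2. Male poly(I:C) LD libraries had 20.9, 17.0, 16.5 and 19.6, and male saline LD libraries 19.0, 15.3, 21.6 and 19.9. Male poly(I:C) LL libraries had 19.8, 20.3, 15.1 and 15.3, and male saline LL libraries 20.9, 19.5, 18.2 and 15.3. Counts per M reads (CPM) are given as mean ± SD with n = 4 mice, and log2 fold changes as estimate ± SE from edgeR with Benjamini-Hochberg adjusted p.

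The libraries differed in genes that mark regions in or beside the dorsal hippocampus. A library's score for a list was the median over its genes of log2 CPM minus the gene's mean over all 32 libraries. Dentate granule cell genes had scores under -1 in 6 libraries, the low dentate libraries, at -3.00 in female saline LD replicate 3, -2.97 in female saline LL replicate 2 and -2.64 in its replicate 3. The other libraries of this kind stood at -1.66 in female poly(I:C) LL replicate 1, -1.06 in female saline LL replicate 4 and -1.09 in male poly(I:C) LD replicate 2. Without them female saline LL keeps replicate 1 alone, so its values then rest on 1 mouse and their spread on the other groups. Striatal genes reached a score of 3.89 in female saline LD replicate 3, thalamic genes 3.08 in female poly(I:C) LL replicate 1 and choroid plexus genes 7.01 in female saline LL replicate 4.

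**Figure D1:**
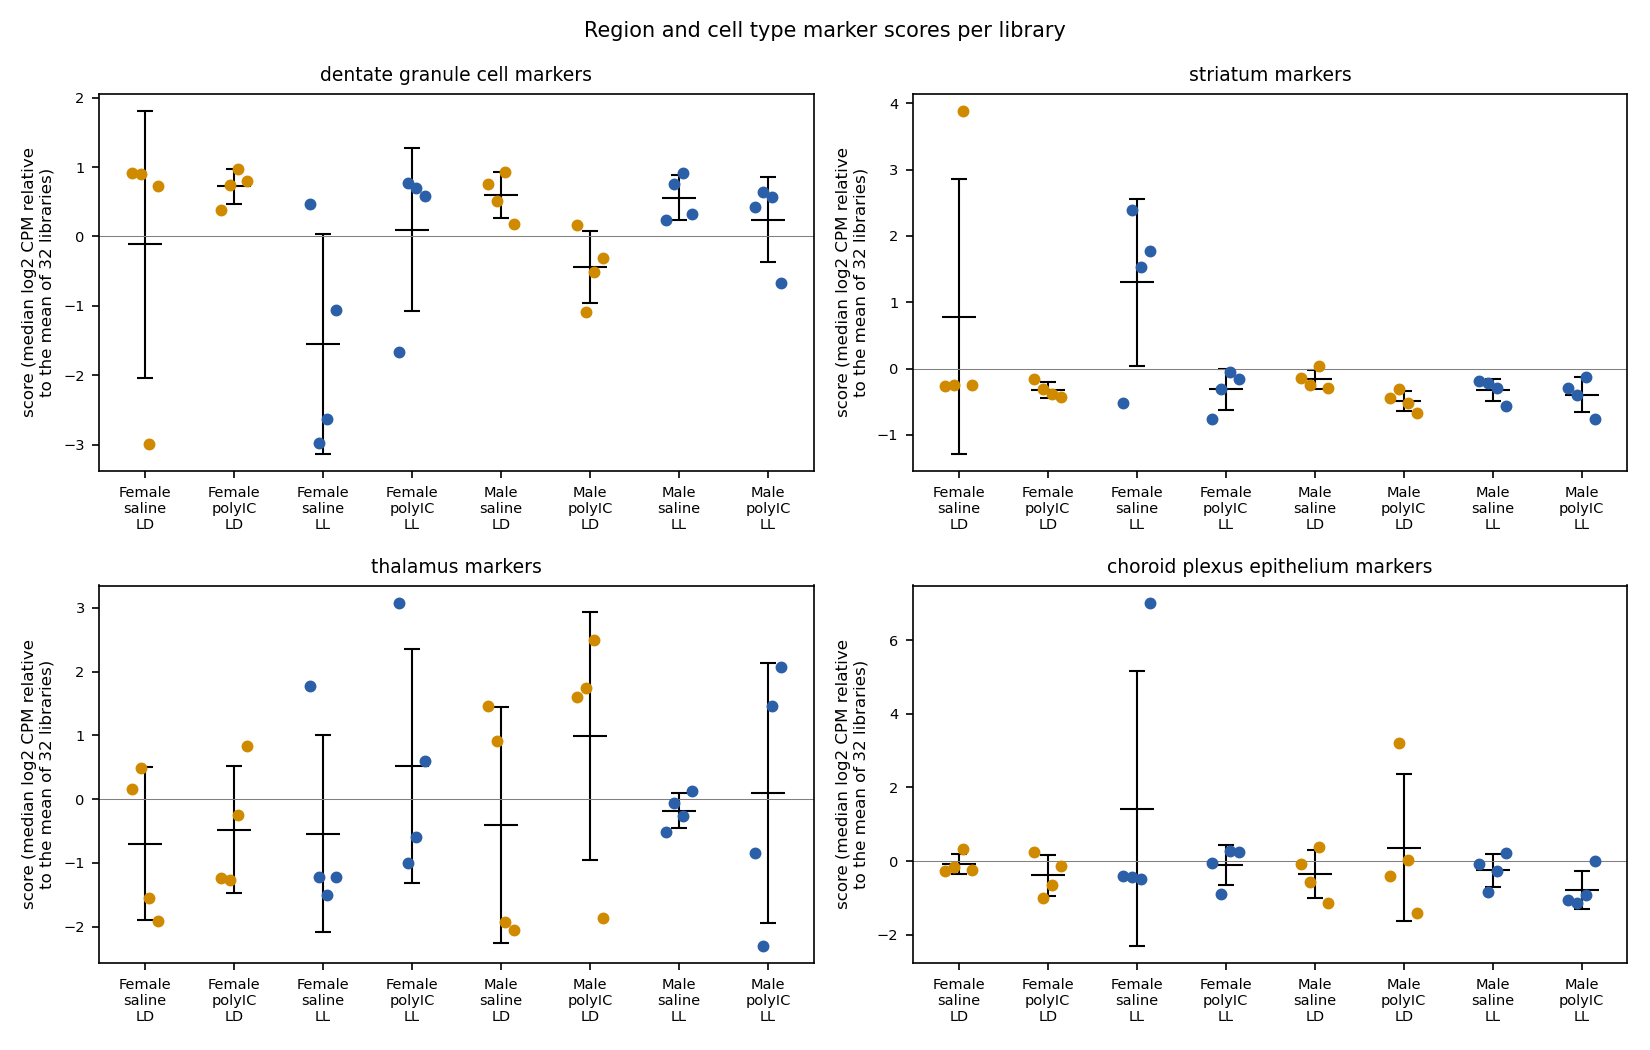
Scores of genes marking dentate granule cells, striatum, thalamus and choroid plexus (log2 units, vertical axis) in each library, by group, LD in orange and LL in blue, with the mean ± SD of 4 libraries as a black bar. Female saline LD replicate 3 has a striatal score of 3.89 and a dentate granule score of -3.00, and female saline LL replicate 4 a choroid plexus score of 7.01.

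Constant light was compared with LD over both sexes and both prenatal treatments, to ask what disrupted lighting in adolescence does to hippocampal expression. Genes of the unfolded protein response, which fold and clear proteins in the endoplasmic reticulum, fell under LL: 14 of 15 were lower, with a median log2 fold change of -0.24. Xbp1, the transcription factor at the head of one arm of that response, fell by 0.41 ± 0.06 on the log2 scale (adjusted p = 0.00572, edgeR). Its level in males was 71.8 ± 13.4 CPM in saline LD, 53.8 ± 4.01 in saline LL, 87.2 ± 11.8 in poly(I:C) LD and 48.6 ± 5.97 in poly(I:C) LL. In females it was 68.3 ± 6.37, 64.3 ± 7.79, 65.6 ± 8.49 and 53.1 ± 3.62 CPM in the same order. Pdia6, a disulfide isomerase, and Hyou1, a chaperone, also fell, with log2 fold changes of -0.35 ± 0.07 and -0.24 ± 0.05 and edgeR adjusted p of 0.0406 and 0.0461.

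Of the list's 15 measured genes 3 fell over all genes tested and 12 fell when adjusted over the list alone. Camera's preset correlation gave the list an adjusted p of 4.08e-23, and adjusted p = 0.0560 with an estimated correlation. Fry, which tests whether the genes move one way on balance, gave an adjusted p of 0.0171. The list's median was -0.02 in saline females, -0.18 in poly(I:C) females, -0.38 in saline males and -0.45 in poly(I:C) males. The sex difference of the light effect passed with camera's preset correlation in both prenatal treatments, at 0.36 in saline and 0.30 in poly(I:C) offspring as female minus male. These differences had adjusted p = 0.704 and 0.550 with an estimated correlation. The saline difference was 0.20 without female saline LL replicate 4 and 0.06 (camera adjusted p = 0.615) without the low dentate libraries. Xbp1 lies on chromosome 11 from 5520659 to 5525893 (ENSMUSG00000020484.19), Pdia6 on chromosome 12 from 17266545 to 17284770 and Hyou1 on chromosome 9 from 44379490 to 44392369, in GRCm38 coordinates from GENCODE.

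**Figure D2:**
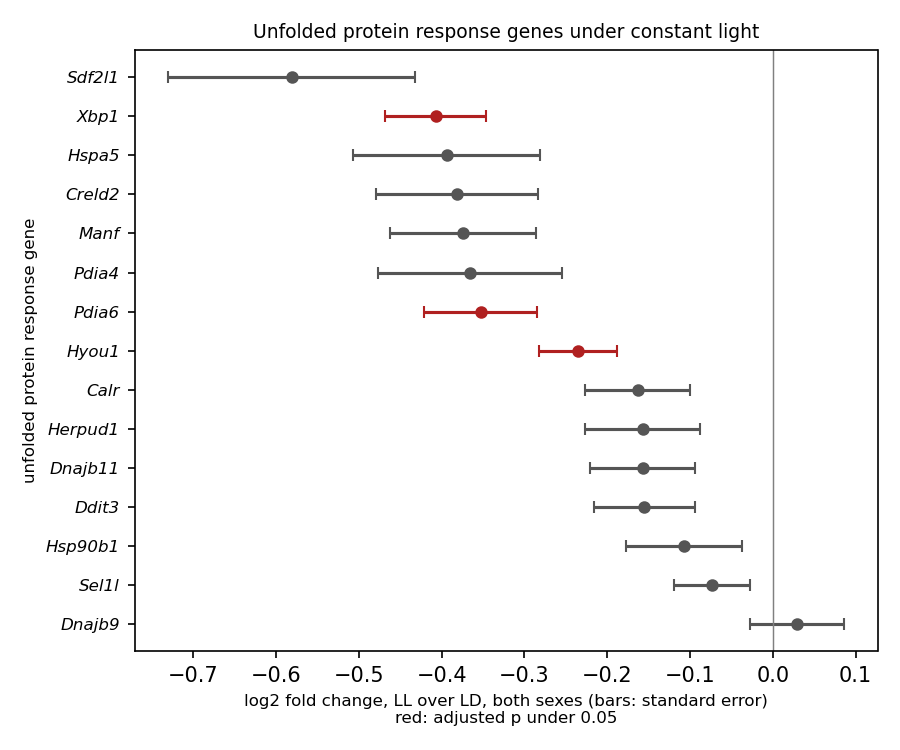
Log2 fold change of 15 unfolded protein response genes, LL over LD across both sexes and treatments, with SE bars (horizontal axis in log2 units). Xbp1, Pdia6 and Hyou1, in red, had an edgeR adjusted p under 0.05, and only Dnajb9 lay above 0.

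Of 17771 genes tested 6 rose and 6 fell under LL over both sexes, a count reached by 4 of 50 splits of the libraries. An unadjusted p under 0.05 was held by 1495. Wnt9a, a secreted Wnt ligand, had a log2 fold change of 0.77 ± 0.14 (adjusted p = 0.0257). Its levels in LD and LL were 7.74 ± 0.98 and 14.3 ± 1.91 CPM in saline males, 8.09 ± 3.95 and 14.7 ± 4.28 in poly(I:C) males, 6.80 ± 0.64 and 8.66 ± 3.07 in saline females and 6.99 ± 1.77 and 13.75 ± 2.72 in poly(I:C) females. Rad51ap2 rose by 0.72 ± 0.12 and Xrra1 by 0.75 ± 0.15 in the edgeR fit, with adjusted p of 0.0180 and 0.0447. Parn, a deadenylase, rose by 0.22, Atp11b by 0.21 and Zfp810 by 0.20, with edgeR adjusted p of 0.0406, 0.0467 and 0.0351. Zbtb40, a zinc finger gene, fell by 0.48 ± 0.07 (adjusted p = 0.00572). Creb1, a transcription factor of activity-dependent expression, had a log2 fold change of -0.21 ± 0.04 and Nfya of -0.38 ± 0.07, with edgeR adjusted p of 0.0227 and 0.0406. Wnt9a lies on chromosome 11 from 59306928 to 59333552 (ENSMUSG00000000126.11), Zbtb40 on chromosome 4 from 136979732 to 137048801 (ENSMUSG00000060862.10) and Creb1 on chromosome 1 from 64532645 to 64604548.

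The count of 12 moved with the method and with single libraries. DESeq2 called 73 genes, limma with voomWithQualityWeights 845, a fit with 1 surrogate variable 48, the stricter filter 25, no filter 5, regional covariates 65 and the libraries without low dentate genes 26. With 1 library left out it ran from 3, as without male saline LD replicate 3, to 37 without female saline LL replicate 4.

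Genes of the circadian clock were tested because constant light removes the daily light signal. Dbp, an output gene of the clock, had a log2 fold change of 0.50 ± 0.10 that did not pass (adjusted p = 0.0552, edgeR). Its levels in LD and LL were 25.7 ± 5.08 and 43.2 ± 12.4 CPM in saline males, 28.3 ± 5.78 and 41.3 ± 6.97 in poly(I:C) males, 33.2 ± 9.01 and 31.9 ± 7.52 in saline females and 25.7 ± 3.69 and 43.6 ± 4.39 in poly(I:C) females. Per2 stood at -0.34 ± 0.09, Nfil3 at -0.24 ± 0.07 and Arntl at -0.19 ± 0.05, none past the threshold over all genes. Adjusted over the list alone, 2 of 23 clock genes rose and 4 fell, and 0 passed over all genes with edgeR. Camera gave the list an adjusted p of 0.163, while fry's test for change in either direction gave 0.00163.

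**Figure D3:**
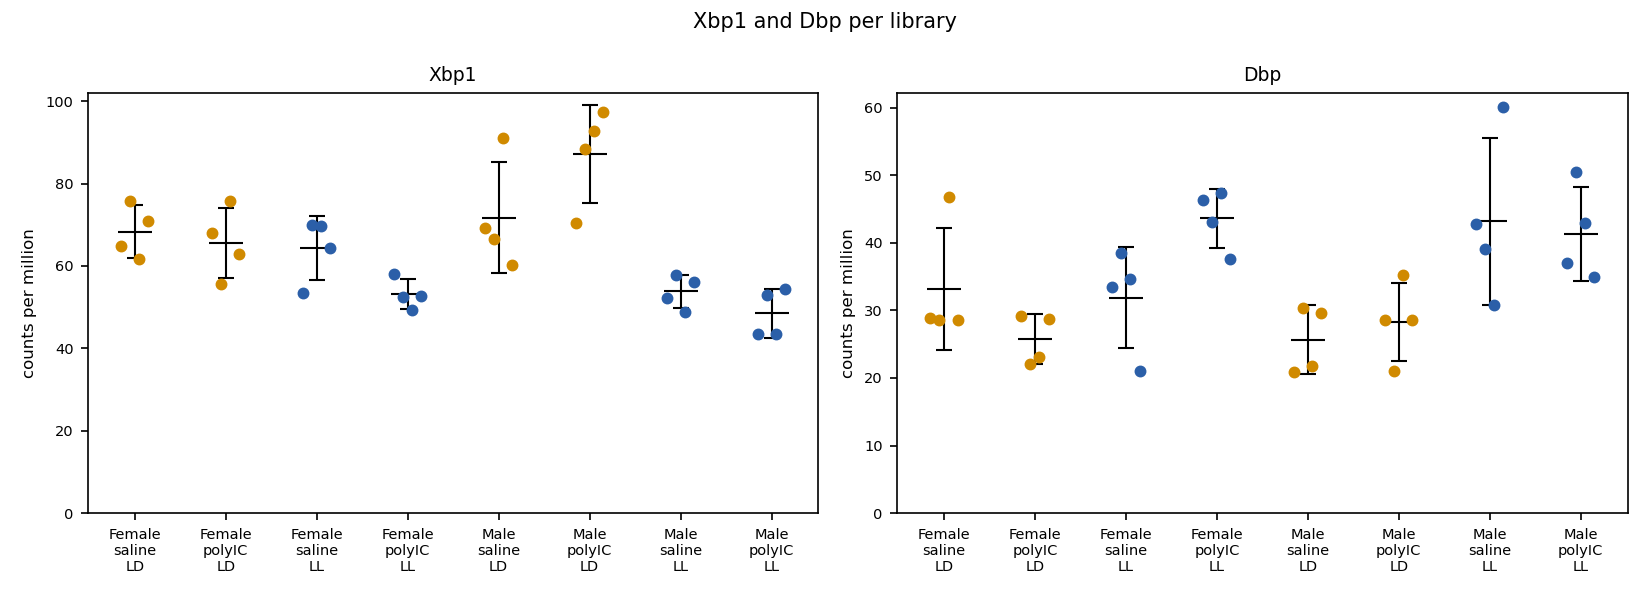
Xbp1 and Dbp in CPM (vertical axis, from 0) for each library by group, with the mean ± SD of 4 libraries. Xbp1 averaged 87.2 in male poly(I:C) LD and 48.6 in male poly(I:C) LL.

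Other lists were also called in LL versus LD over both sexes. Genes marking CA2 and CA3 pyramidal neurons rose with a median of 0.37, 11 of 12 higher (camera adjusted p = 0.00464; adjusted p = 0.900 with an estimated correlation). Nuclear-encoded respiratory chain genes rose with a median of 0.07, 69 of 77 higher. Heat shock genes fell with a median of -0.07, 12 of 15 lower, and autism-associated genes with -0.04, 24 of 34 lower. They had camera adjusted p of 3.9e-06, 0.00475 and 0.00956, and adjusted p = 0.900 with an estimated correlation each. No member of these lists passed edgeR's test over all genes, and adjusted over the list alone 1 heat shock and 1 autism-associated gene fell. The heat shock median was -0.15 and the autism-associated one -0.03 without the low dentate libraries (the latter at camera adjusted p = 0.204). The CA2 and CA3 median was 0.20 without female poly(I:C) LL replicate 1, and the respiratory chain median 0.03 without male saline LL replicate 4.

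Prenatal poly(I:C) was compared with saline over both sexes and lighting conditions, to ask for a lasting trace of maternal immune activation. Striatal genes fell with a median of -1.08, 11 of 11 lower, and neocortical genes with a median of -0.34, 13 of 15 lower. Striatal scores were 3.89 in female saline LD replicate 3 and 2.39, 1.54 and 1.78 in female saline LL replicates 2, 3 and 4, and at most 0.034 in every other library. Genes of adult neurogenesis fell with a median of -0.31, and thalamic genes rose with a median of 0.94. Mitochondrially encoded genes rose with a median of 0.16, 7 of 8 higher, and 6 of them passed when adjusted over the list alone. By camera 14 of 34 lists passed, with adjusted p of 1.09e-09 for striatum, 3.86e-06 for neocortex, 6.43e-05 for neurogenesis and 0.000116 for thalamus. With an estimated correlation these were adjusted p = 0.312, 0.312, 0.338 and 0.629, and adjusted p = 0.312 for the mitochondrial genes. Without the low dentate libraries, with 1 female saline LL library left, the striatal, neocortical, neurogenesis and thalamic medians were 0.02, -0.13, -0.06 and 0.06. Regional covariates include the striatal and thalamic scores and cannot test those lists. edgeR called 0 genes, with 1775 at an unadjusted p under 0.05; DESeq2 called 27 and limma with voomWithQualityWeights 518. Without female saline LL replicate 1 the edgeR count was 2.

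In males under LD, poly(I:C) offspring were compared with saline offspring. Myelin genes rose with a median log2 fold change of 1.28, and 16 of 16 were higher and passed when adjusted over the list alone. Dentate granule genes fell with a median of -0.99, 11 of 11 lower and 8 adjusted over the list alone, including Plk5 at -1.31 ± 0.32. Heat shock genes rose with a median of 0.34, 15 of 15 higher and 9 adjusted over the list alone. Thalamic genes, which mark a neighbouring and heavily myelinated region, rose alongside the myelin genes with a median of 1.40, 11 of 11 higher.

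Camera gave adjusted p of 4.16e-10 for myelin, 1.49e-07 for dentate granule, 1e-06 for heat shock and 0.00638 for thalamic genes. These were adjusted p = 0.689, 0.689, 0.689 and 0.739 with an estimated correlation. By camera 12 lists passed, oligodendrocyte precursor genes among them with a median of 0.55 and adult neurogenesis genes with -0.42, which had adjusted p = 0.689 and 0.739 with an estimated correlation. With regional covariates the medians were 0.41 for myelin, -0.30 for dentate granule, 0.19 for heat shock and 0.18 for oligodendrocyte precursor genes, each still called, and 0.08 for adult neurogenesis genes (camera adjusted p = 0.435). The thalamic median was 0.91 (camera adjusted p = 0.0868) without male poly(I:C) LD replicate 3, and the myelin median 0.77 without its replicate 2. edgeR called 0 of 17210 genes, with Adck5 lowest in p at -0.84 ± 0.14 (adjusted p = 0.115). At an unadjusted p under 0.05 were 3883, but 915 with regional covariates. DESeq2 called 1088 genes, 580 higher and 508 lower, and limma with voomWithQualityWeights 0. The edgeR count was 1 without male poly(I:C) LD replicate 1 and 1 without male poly(I:C) LL replicate 4.

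Under LL the same treatments were compared in males. Myelin genes rose with a median of 0.40, 16 of 16 higher, and oligodendrocyte precursor genes with 0.16, while neocortical genes fell with a median of -0.19. These lists had camera adjusted p of 0.000241, 0.0350 and 0.0335, and adjusted p = 0.924 with an estimated correlation each. Glucocorticoid-responsive genes rose with a median of 0.14 and mitochondrially encoded genes with 0.11, which had adjusted p = 0.309 and 0.924 with an estimated correlation. Without male poly(I:C) LL replicate 4 the myelin and oligodendrocyte precursor medians were 0.11 and 0.03 (camera adjusted p = 0.236 and 0.543). The neocortical median was -0.0015 without male saline LL replicate 1 and the mitochondrial one 0.06 without its replicate 2 (camera adjusted p = 0.336 and 0.218). The noncoding RNA Bc1 had -3.15 ± 0.78 and did not pass. edgeR called 0 genes, with 274 at an unadjusted p under 0.05. DESeq2 and limma with voomWithQualityWeights called 0.

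Constant light was compared with LD in male saline offspring. Unfolded protein response genes fell with a median of -0.38, 14 of 15 lower and 9 adjusted over the list alone, Hyou1 at -0.38 ± 0.10 and Xbp1 at -0.41 ± 0.13. Respiratory chain genes rose with a median of 0.14, 67 of 77 higher, mitochondrially encoded genes with 0.24, ribosomal protein genes with 0.13 and microglial genes with 0.17. Camera gave adjusted p of 5.37e-11, 2.21e-08, 9.49e-05, 1.93e-06 and 9.49e-05, and adjusted p = 0.825 with an estimated correlation for all of these but the respiratory chain genes at 0.862. The CA2 and CA3 list, at 0.43, and the autism-associated list, at -0.08, also passed by camera, with adjusted p = 0.862 and 0.934 with an estimated correlation. Without male saline LL replicate 4 the respiratory chain, CA2 and CA3, and autism-associated medians were 0.02, 0.215 and -0.0072 (camera adjusted p = 0.219, 0.199 and 0.665), the ribosomal protein median 0.06 and the mitochondrial one 0.15. The unfolded protein response median was -0.20 without male saline LD replicate 3. Bc1 stood at 3.52 ± 0.79 and Inmt at 2.27 ± 0.46 (adjusted p = 0.763 each, edgeR), Bc1 from 1835 ± 1962 CPM in saline LL against 160 ± 45.2 in saline LD. edgeR called 0 genes, with 1094 at an unadjusted p under 0.05; DESeq2 called 3 and limma with voomWithQualityWeights 0.

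In male poly(I:C) offspring LL was compared with LD. Zfp46, a zinc finger gene on chromosome 4 from 136284683 to 136293942 (ENSMUSG00000051351.14), rose from 30.9 ± 4.98 to 58.0 ± 12.3 CPM, a log2 fold change of 0.92 ± 0.13 (adjusted p = 0.0497, edgeR). All 15 unfolded protein response genes were lower, with a median of -0.45, and 13 fell when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, averaged 453 ± 76.9 CPM in LD and 234 ± 52.1 in LL, a log2 fold change of -0.93 ± 0.18 that did not pass over all genes. Myelin genes fell with a median of -1.13, 16 of 16 lower and 15 adjusted over the list alone, and heat shock genes with -0.36, 15 of 15 lower and 7 adjusted over the list alone. Choroid plexus genes with -2.10 and thalamic genes with -0.82 fell alongside them, and dentate granule genes rose with 0.66.

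By camera the unfolded protein response list had an adjusted p of 1.55e-20, myelin 4.85e-11, heat shock 2.47e-09, choroid plexus 0.00435, thalamus 0.0473 and dentate granule 1.22e-05. With an estimated correlation these were adjusted p = 0.224, 0.425, 0.323, 0.682, 0.876 and 0.425. Without male poly(I:C) LD replicate 2 the choroid plexus median was -0.24 (camera adjusted p = 0.684) and the myelin one -0.59, and without its replicate 3 the thalamic one was -0.29 (camera adjusted p = 0.387). With regional covariates the myelin, heat shock and dentate granule medians were -0.44, -0.23 and 0.18, each still called. Fry gave the unfolded protein response list an adjusted p of 0.0247. edgeR called 2 genes, both higher, and 2563 had an unadjusted p under 0.05. The other called gene, D330025C20Rik (ENSMUSG00000102260.1), at 2.64 ± 0.40 with an edgeR adjusted p of 0.0497, was named after its values were seen. DESeq2 called 215 genes and limma with voomWithQualityWeights 7. The edgeR count was 285 without male poly(I:C) LL replicate 4, 61 without male poly(I:C) LD replicate 1, 3 without male saline LD replicate 3 and 0 without any one of the other male libraries, and also 0 with RLE factors, the stricter filter, regional covariates or the low dentate libraries left out.

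Male mice with both exposures, poly(I:C) and LL, were compared with mice with neither. Unfolded protein response genes fell with a median of -0.42, 14 of 15 lower and 8 adjusted over the list alone, Pdia6 at -0.55 ± 0.13. Glucocorticoid-responsive genes rose with a median of 0.16, 13 of 16 higher, with the metallothionein genes Mt2 at 0.57 ± 0.15 and Mt1 at 0.37 ± 0.12. Mitochondrially encoded genes rose with a median of 0.32, 8 of 8 higher and 6 adjusted over the list alone. Dentate granule genes fell with a median of -0.25. The glucocorticoid-responsive call was the only list call kept among all 21 comparisons with an estimated correlation (adjusted p = 0.0368; camera's preset correlation 0.000576, fry 0.0187), and 1 member rose when adjusted over the list alone. The others had adjusted p = 0.230, 0.170 and 0.803 with an estimated correlation, in the order given. The dentate granule median was -0.02 (camera adjusted p = 0.688) without male poly(I:C) LL replicate 4. edgeR called 0 genes, with 954 at an unadjusted p under 0.05; DESeq2 called 1 and limma with voomWithQualityWeights 0.

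The single exposures were compared with each other, poly(I:C) under LD with saline under LL. In males 50 genes were higher in poly(I:C) LD and 46 lower. Xbp1 was higher by 0.69 ± 0.13 and Hspa5 by 0.89 ± 0.18 (edgeR adjusted p = 0.0407 and 0.0474), and 15 of 15 unfolded protein response genes were higher with a median of 0.46. Gpr17, a receptor of maturing oligodendrocytes, was higher by 0.98 ± 0.18, and the heat shock genes Bag3 and Chordc1 by 0.58 ± 0.12 and 0.44 ± 0.09. Rpl19 and Rps19, of the ribosome, stood at -0.58 ± 0.11 and -0.53 ± 0.11. Myelin genes were higher with a median of 1.56, thalamic genes with 1.95 and dentate granule genes lower with -0.98 in the same comparison.

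These 5 genes had edgeR adjusted p of 0.0407, 0.0489, 0.0489, 0.0418 and 0.0458 for Gpr17, Bag3, Chordc1, Rpl19 and Rps19. Adjusted over the list alone, 14 unfolded protein response, 13 heat shock, 16 myelin and 8 dentate granule genes passed. Camera called 10 lists, and the myelin, heat shock, unfolded protein response and dentate granule lists had adjusted p = 0.430 with an estimated correlation, the thalamic list 0.796. With regional covariates the myelin and dentate granule medians were 0.87 and -0.50, each still called, and the thalamic median was 1.37 (camera adjusted p = 0.109) without male poly(I:C) LD replicate 3. Of 17210 genes 4365 had an unadjusted p under 0.05. DESeq2 called 1823, limma with voomWithQualityWeights 26, a fit of only these 2 groups 4 and one with 1 surrogate variable 14. The stricter filter gave 246, while regional covariates and leaving out the low dentate libraries gave 0. The count was 1916 without male poly(I:C) LD replicate 4, 1290 without its replicate 1, 1139 without male poly(I:C) LL replicate 4, 61 without male saline LD replicate 4 and 8 or fewer without any one of the other male libraries save male saline LD replicate 3, at 78.

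In females under LD poly(I:C) was compared with saline. Striatal genes were lower in poly(I:C) offspring with a median of -2.76, 11 of 11 lower and each passing when adjusted over the list alone. Glucocorticoid-responsive genes were higher with a median of 0.24, 14 of 16 higher, and oligodendrocyte precursor genes lower with -0.19. These lists had camera adjusted p of 4.09e-09, 0.000191 and 0.00273 in that order, and adjusted p = 0.872 with an estimated correlation each, as for all 10 lists called. Striatal scores in saline LD were -0.27, -0.25, 3.89 and -0.25, and -0.43 to -0.16 in poly(I:C) LD. Without female saline LD replicate 3 the striatal median was -0.07 (camera adjusted p = 0.354), the oligodendrocyte precursor one -0.10 (camera adjusted p = 0.0543) and the neocortical gene Ccn2 went from -1.64 ± 0.87 to 0.31. edgeR called 0 of 17114 genes, with 380 at an unadjusted p under 0.05. DESeq2 and limma with voomWithQualityWeights called 0.

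Under LL the same treatments were compared in females. Ependymal genes were lower in poly(I:C) offspring with a median of -3.69, choroid plexus genes with -5.31 and striatal genes with -2.10, while dentate granule genes were higher with 1.32. Immediate early genes, induced by neuronal activity, were lower with a median of -0.59, 19 of 24 lower, among them Npas4 at -1.96 ± 0.71. Unfolded protein response genes were lower with a median of -0.29, 14 of 15, and astrocyte genes higher with 0.28, 13 of 14. Camera called 16 lists, with adjusted p of 1.01e-06 for ependymal, 0.00303 for choroid plexus, 2.14e-05 for striatal, 0.00159 for dentate granule, 0.000188 for immediate early, 2.14e-05 for unfolded protein response and 0.000237 for astrocyte genes. With an estimated correlation all 16 had adjusted p = 0.537 to 0.688. The choroid plexus median was 0.47 and the unfolded protein response one -0.18 without female saline LL replicate 4. With regional covariates the medians were -0.92 for ependymal, -0.22 for immediate early and 0.13 for astrocyte genes, each still called, and 0.44 for dentate granule genes (camera adjusted p = 0.0527). Without the low dentate libraries, with 1 saline LL library left, the ependymal, striatal, immediate early, unfolded protein response and astrocyte medians were -0.37, 0.42, 0.11, -0.09 and 0.07. edgeR called 0 genes, with 1902 at an unadjusted p under 0.05; DESeq2 called 92 and limma with voomWithQualityWeights 5743, and the edgeR count was 24 without female saline LL replicate 1 and 2 without female saline LD replicate 3.

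LL was compared with LD in female saline offspring. Choroid plexus genes were higher in LL with a median of 4.28, ependymal genes with 1.56 and myelin genes with 0.81, while dentate granule genes were lower with -1.35. Ttr, the main transcript of the choroid plexus, averaged 2514 ± 5023 CPM in LL and 8.53 ± 1.93 in LD. Microglial genes were lower with a median of -0.23, 21 of 23, and ribosomal protein genes with -0.16, 71 of 80. Camera gave these 6 lists adjusted p of 0.00640, 0.000264, 7.65e-06, 0.000199, 7.65e-06 and 5.72e-10, and adjusted p = 0.728 with an estimated correlation each, as for all 10 lists called. edgeR called 0 genes, with 1591 at an unadjusted p under 0.05; DESeq2 called 3 and limma with voomWithQualityWeights 5777. The ependymal median was 0.13 without the low dentate libraries, with 1 saline LL library left. The edgeR count was 1 without female saline LD replicate 3 and 1 without female poly(I:C) LL replicate 1. Without female saline LL replicate 4 the choroid plexus, ependymal and myelin medians were -0.40, 0.65 and 0.28. The dentate granule median was -0.67, still called, and the myelin one 0.27 (camera adjusted p = 0.150) with regional covariates, and without female saline LD replicate 4 the microglial one was -0.069.

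In female poly(I:C) offspring LL against LD gave higher thalamic genes, with a median of 1.76, and higher myelin genes, with 0.67. Genes of CA1 pyramidal neurons were lower with -0.60, 7 of 7, and those of CA2 and CA3 higher with 0.58, 10 of 12. Unfolded protein response genes were lower with a median of -0.18, 12 of 15, and Dbp stood at 0.75 ± 0.19 without passing. Camera gave adjusted p of 0.000609, 1.75e-05, 0.0256, 0.0127 and 0.000609 in that order of lists, and adjusted p = 0.911 with an estimated correlation for all 9 lists called. Without female poly(I:C) LL replicate 1 the thalamic, myelin, and CA2 and CA3 medians were -0.02, 0.06 and 0.03 (camera adjusted p = 0.824, 0.727 and 0.571). The CA1 median was -0.18 without female poly(I:C) LD replicate 1 and the unfolded protein response one -0.12 without female poly(I:C) LL replicate 3 (camera adjusted p = 0.428 and 0.0504). edgeR called 0 genes, with 482 at an unadjusted p under 0.05; DESeq2 and limma with voomWithQualityWeights called 0.

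Female mice with both exposures were compared with mice with neither. Striatal genes were lower with a median of -2.46 and thalamic genes higher with 1.68. Adult neurogenesis genes were lower with -0.48, 12 of 13, with the cell-cycle gene Mki67 at -1.46 ± 0.53, and unfolded protein response genes with -0.32, 14 of 15. These lists had camera adjusted p of 2.4e-07, 0.000129, 1.38e-06 and 1e-09, and adjusted p = 0.879, 0.879, 0.633 and 0.633 with an estimated correlation. The striatal median was -0.12 without female saline LD replicate 3 and the thalamic one 0.07 without female poly(I:C) LL replicate 1 (camera adjusted p = 0.794 and 0.833). Neurogenesis genes had -0.13 without the low dentate libraries (camera adjusted p = 0.0751). edgeR called 0 genes, with 595 at an unadjusted p under 0.05; DESeq2 called 0 and limma with voomWithQualityWeights 3, and the edgeR count was 1 with the low dentate libraries left out.

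Between the single exposures in females, myelin genes were lower in poly(I:C) LD than in saline LL with a median of -1.16, 16 of 16 lower and each passing when adjusted over the list alone. Ribosomal protein genes were higher with 0.18, 73 of 80, and dentate granule genes with 1.66, while ependymal genes were lower with -2.84. Camera gave adjusted p of 6.36e-07, 3.94e-08, 0.000468 and 0.000396, and adjusted p = 0.806 with an estimated correlation for all 13 lists called. Regional covariates gave myelin and ependymal medians of -0.18 and -0.34 (camera adjusted p = 0.263 and 0.287) and a dentate granule one of 0.45, still called. Without female saline LL replicate 4 the myelin and ependymal medians were -0.65 and -1.79. Without the low dentate libraries, with 1 saline LL library left, they were -0.46 and 0.79. edgeR called 0 genes, with 3881 at an unadjusted p under 0.05; DESeq2 called 261 and limma with voomWithQualityWeights 5890. The edgeR count was 666 without female saline LL replicate 1, 22 without female poly(I:C) LL replicate 1 and 2 without female saline LD replicate 3.

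Whether the light effect differed between poly(I:C) and saline offspring was tested as an interaction, the question of a second hit after the first. In males myelin genes had an interaction median of -0.82, 16 of 16 lower, unfolded protein response genes of -0.25, 15 of 15 lower, and dentate granule genes of 0.78, 11 of 11 higher. In females immediate early genes had -0.60, 22 of 24 lower, clock genes 0.28, 18 of 23 higher, and choroid plexus genes -4.10. Over both sexes heat shock genes had -0.17, 14 of 15 lower, and choroid plexus genes -3.63. Camera called 10 lists in males, 15 in females and 8 over both sexes, and these had adjusted p = 0.776 to 0.786, 0.475 to 0.692 and 0.769 to 0.820 with an estimated correlation. With regional covariates the male medians were 0.02 for myelin, -0.10 for unfolded protein response and 0.03 for dentate granule genes (camera adjusted p = 0.980, 0.103 and 0.726). Without female saline LL replicate 4 the female clock and choroid plexus medians were 0.09 and 0.59 and the choroid plexus median over both sexes -0.95 (camera adjusted p = 0.0650, 0.0578 and 0.0598). The female immediate early median was -0.39 without female poly(I:C) LD replicate 1. Without the low dentate libraries, with 1 female saline LL library left, the female immediate early, clock and choroid plexus medians were 0.048, 0.00039 and 0.48. edgeR called 0 genes in males, in females and over both sexes, with 856, 316 and 882 at an unadjusted p under 0.05. DESeq2 called 0, 0 and 1, and limma with voomWithQualityWeights 0, 2684 and 2100.

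The sexes were compared for each effect, as female minus male. For poly(I:C) under LD myelin genes had a difference of -1.67, 16 of 16 lower, and for LL in poly(I:C) offspring of 1.81, 16 of 16 higher. Ribosomal protein genes differed by -0.28 for LL in saline offspring, 66 of 80 lower and 27 passing when adjusted over the list alone. These lists had camera adjusted p of 1.52e-10, 5.56e-12 and 4.61e-17, and adjusted p = 0.828, 0.550 and 0.355 with an estimated correlation. Striatal genes stood at -3.14 in the first of these and thalamic genes at 2.40 in the second. The striatal difference was 0.056 (camera adjusted p = 0.969) without female saline LD replicate 3, and the thalamic one 0.76 without female poly(I:C) LL replicate 1. Myelin differences were -0.79 and 0.73 without the low dentate libraries, both still called. edgeR called 0 genes for poly(I:C) under LD and LL and for LL in saline and poly(I:C) offspring, with 2262, 1231, 1423 and 2201 at an unadjusted p under 0.05. DESeq2 called 1, 2, 0 and 0, and limma with voomWithQualityWeights 0, 3266, 4157 and 0; without female saline LL replicate 1 the second edgeR count was 2.

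Across genes, which are not independent replicates, log2 fold changes of poly(I:C) under LD and under LL had a Pearson correlation of 0.63 in females and 0.37 in males. Those of LL in saline and in poly(I:C) offspring had 0.31 and 0.32. Between females and males the correlation was -0.27 for poly(I:C) under LD, 0.06 under LL, -0.03 for LL in saline offspring, -0.40 for LL in poly(I:C) offspring and 0.28 for both exposures against neither. Over genes with a mean of at least 10 CPM these 9 values were 0.57, 0.53, 0.50, 0.33, -0.28, 0.15, -0.03, -0.55 and 0.44, in the order given. The Spearman correlation between sexes for poly(I:C) under LL was -0.04 over all genes.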

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

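The test of constant light for the striatal pattern, both tests of read depth, and the test of constant light in both sexes for the unfolded protein response were chosen after the result was seen; the tests of regional covariates, low-dentate libraries, single libraries, splits and RNAs without a poly(A) tail were written before theirs.

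Chance flags about 1 in 20 groups as having a library apart, and 35 of 432 group values did here by Dixon's test for 4 values. The genes Zfp46, Dbp, Bc1, Ttr, Dsp, Xist and Shox2 were added to this test after their values were seen. Female poly(I:C) LL replicate 4 stood apart with 21.1 M gene reads. Female saline LD replicate 3 stood apart with scores of -0.090 for core clock, 0.32 for choroid plexus, 2.67 for ependymal, -3.00 for dentate granule and 3.89 for striatum, 46.7 CPM of Dbp, 1.28 CPM of Dsp and 1563 CPM of Xist. Female saline LL replicate 1 stood apart with scores of -0.37 for microglia and 1.77 for thalamus. Male poly(I:C) LL replicate 4 stood apart with scores of 0.21 for oligodendrocyte precursor, -0.67 for dentate granule and 0.19 for heat shock and 85.7 CPM of Dsp. Female saline LL replicate 4 stood apart with scores of 7.01 for choroid plexus, 0.92 for interferon response, 0.51 for cytokine and -0.29 for synaptic vesicle and scaffold and 4.15 CPM of Wnt9a. Female poly(I:C) LL replicate 1 stood apart with scores of 0.14 for ependymal, 1.19 for CA2 and CA3, -1.66 for dentate granule, -1.65 for GABAergic interneuron, -1.06 for neurogenesis and -0.18 for ribosomal protein and 35.5 CPM of Dsp. Male poly(I:C) LD replicate 4 stood apart with a score of -0.86 for CA2 and CA3, its replicate 3 with -0.21 for glucocorticoid-responsive. Female poly(I:C) LD replicate 1 stood apart with a score of 0.11 for interferon response, its replicate 3 with 0.18 for ribosomal protein. Male saline LD replicate 2 stood apart with a score of 0.32 for antigen presentation, its replicate 3 with 0.46 for unfolded protein response. Male poly(I:C) LL replicate 2 stood apart with a score of 0.11 for cytokine, male saline LD replicate 4 with 228 CPM of Bc1.

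Effects of LL between treatments, or of either exposure between sexes, differed for the lists below by camera with the preset correlation, given as median log2 difference, and each of these calls was lost with an estimated correlation. In the interaction in females medians were 0.28 for core clock, -0.60 for immediate early, 0.17 for microglia, 0.27 for astrocyte, 0.19 for endothelial, 0.22 for pericyte, -4.10 for choroid plexus, -2.45 for ependymal, 1.11 for dentate granule, 1.05 for thalamus, -0.16 for glucocorticoid-responsive, 0.079 for GABA receptor, -0.14 for heat shock, -0.23 for unfolded protein response and 0.091 for ribosomal protein. In the interaction in males medians were -0.20 for microglia, -0.82 for myelin, -0.34 for oligodendrocyte precursor, -2.23 for choroid plexus, -0.58 for CA2 and CA3, 0.78 for dentate granule, 0.33 for neurogenesis, -0.26 for heat shock, -0.25 for unfolded protein response and -0.12 for respiratory chain. In the interaction over both sexes medians were -0.47 for immediate early, -0.46 for myelin, -3.63 for choroid plexus, -1.22 for ependymal, 0.95 for dentate granule, -0.17 for heat shock, -0.20 for unfolded protein response and -0.057 for respiratory chain. In the sex difference in poly(I:C) versus saline under LD medians were -0.24 for microglia, -1.67 for myelin, -0.74 for oligodendrocyte precursor, -2.87 for ependymal, -1.08 for CA2 and CA3, 1.22 for dentate granule, -3.14 for striatum, -0.35 for heat shock and -0.27 for unfolded protein response. In the sex difference in poly(I:C) versus saline under LL medians were -0.62 for immediate early, 0.16 for astrocyte, -0.88 for myelin, -0.40 for oligodendrocyte precursor, -5.05 for choroid plexus, -4.04 for ependymal, 1.56 for dentate granule, -1.85 for striatum, -0.22 for heat shock, -0.24 for unfolded protein response and 0.16 for ribosomal protein. In the sex difference in LL versus LD in saline offspring medians were 0.39 for immediate early, -0.39 for microglia, -0.30 for astrocyte, 1.05 for myelin, 0.45 for oligodendrocyte precursor, 4.69 for choroid plexus, 1.71 for ependymal, -1.32 for dentate granule, 0.29 for interferon response, 0.27 for heat shock, 0.36 for unfolded protein response, -0.10 for respiratory chain, -0.30 for mitochondrially encoded and -0.28 for ribosomal protein. In the sex difference in LL versus LD in poly(I:C) offspring medians were 0.12 for core clock, 1.81 for myelin, 0.78 for oligodendrocyte precursor, 2.76 for choroid plexus, -0.98 for dentate granule, 2.40 for thalamus, 0.30 for interferon response, -0.38 for glucocorticoid-responsive, -0.48 for neurogenesis, 0.36 for heat shock, 0.30 for unfolded protein response and -0.18 for ribosomal protein.

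Female saline LL replicates 2, 3 and 4 had higher striatal and ependymal scores than the other female libraries save saline LD replicate 3. Lower read depth is argued against by the median of 16.3 M gene reads, within the range of the other female libraries. An effect of constant light in saline offspring alone cannot be told from a difference between single libraries. Only replicate 3 had a high striatal score in saline LD, 3.89, and 1 library excludes nothing. Neighbouring tissue in the dissected piece was not tested. Dentate granule genes, outside the pattern, scored -2.97, -2.64 and -1.06 in saline LL replicates 2, 3 and 4, as such tissue would give. Female poly(I:C) LL replicate 1 also scored low, at -1.66, without high striatal genes. Such tissue stays open, as do differences between mice, since no label records either.

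Unfolded protein response genes were lower under LL than LD over both sexes. Neighbouring tissue is argued against as the whole cause by the median of -0.24 with regional covariates, the low dentate libraries by -0.31 without them, with 1 female saline LL library left, and a single library by -0.21 as the smallest of 32 fits. Of 50 splits of the libraries within sex and treatment 1, the real one, gave a median as large (-0.24, highest other -0.18). Again only the real one gave a camera p as small for any of the 34 lists (1.2e-24, smallest other 5.61e-22). Chance is argued against for this comparison taken alone. No allowance was made for the 21 comparisons, and an estimated correlation gave adjusted p = 0.0560. Constant light may be behind it. Saline females showed no clear fall, with the highest of the 4 medians, -0.018, and a mean score of 0.12 in LL against 0.083 in LD. A difference in collection time or handling stays open, as the labels give neither.

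Bc1, a noncoding RNA of neurons, was higher in male saline LL replicates 3 and 4 than in the other male libraries, 3479 against 197 CPM on average. Less complete selection of polyadenylated RNA stays open. The 18 RNAs tested as lacking a poly(A) tail were mostly histone genes, many at low levels. Their median log2 ratio was -0.035 (9 higher, -0.86 to 0.86, Bc1 4.15). Lower read depth is argued against by the 18.2 M gene reads of the deeper library. No biological explanation was tested, since the other libraries of the group do not share the level.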

How the results depend on the processing

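The regional covariates and the omission of low-dentate libraries were chosen after the data were seen; the other alternatives were fixed before. Of 692 results for genes named by the fixed rule, 690 kept their direction and their side of the threshold with RLE factors, 681 without a filter on low counts and 632 with the stricter filter, where the rest crossed the threshold or were no longer tested. DESeq2 kept 607 and voomWithQualityWeights 490, with 181 more past the threshold and 14 turned, and 67 turned without the low dentate libraries. Of 216 list results, 214 kept their call with RLE factors, but 215 lost it with an estimated correlation and 211 by fry, which asks another question. Without the low dentate libraries 122 of them kept their call and direction, 57 lost the call and 37 turned, and with regional covariates 123 kept both, 69 lost the call and 24 turned. The unfolded protein response in LL versus LD over both sexes kept its direction and its call by camera's preset correlation under every alternative run, with medians of -0.31 to -0.21. At this size the simulation recovered too few genes changed by 1.5-fold to rule out small changes in single genes. Large ones can be missed where libraries of a group differ. For the values below, given as log2 fold changes or counts, the cause was not tested. A list's sign is that of its test, so a median close to 0 can keep its sign.

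DESeq2 called 92 genes for poly(I:C) versus saline under LL in females, 3 for LL versus LD in saline offspring in females, 261 for poly(I:C) LD versus saline LL in females, 1088 for poly(I:C) versus saline under LD in males and 3 for LL versus LD in saline offspring in males. It also called 215 for LL versus LD in poly(I:C) offspring in males, 1 for poly(I:C) LL versus saline LD in males, 1823 for poly(I:C) LD versus saline LL in males, 27 for poly(I:C) versus saline over both sexes and 73 for LL versus LD over both sexes. It called 1 for the interaction over both sexes, 1 for the sex difference in poly(I:C) versus saline under LD and 2 for the sex difference in poly(I:C) versus saline under LL. A fit of only the 2 groups compared called 1 genes for poly(I:C) versus saline under LD in males, 1 for poly(I:C) LL versus saline LD in males and 4 for poly(I:C) LD versus saline LL in males. edgeR with no filter on low counts called 1 genes for LL versus LD in saline offspring in males and 5 for LL versus LD over both sexes. edgeR with the stricter filter called 0 genes for LL versus LD in poly(I:C) offspring in males, 246 for poly(I:C) LD versus saline LL in males and 25 for LL versus LD over both sexes. edgeR with RLE factors called 0 genes for LL versus LD in poly(I:C) offspring in males. Blocking by replicate number was tried although the numbers do not pair the mice. In males it called 0 genes for LL versus LD in poly(I:C) offspring and 0 for poly(I:C) LD versus saline LL.

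limma with voomWithQualityWeights called 5743 genes for poly(I:C) versus saline under LL in females, 5777 for LL versus LD in saline offspring in females, 3 for poly(I:C) LL versus saline LD in females, 5890 for poly(I:C) LD versus saline LL in females and 2684 for the interaction in females. It also called 7 for LL versus LD in poly(I:C) offspring in males, 26 for poly(I:C) LD versus saline LL in males, 518 for poly(I:C) versus saline over both sexes, 845 for LL versus LD over both sexes and 2100 for the interaction over both sexes. It called 3266 for the sex difference in poly(I:C) versus saline under LL and 4157 for the sex difference in LL versus LD in saline offspring. Ccn2 was at 0.067 in poly(I:C) versus saline under LD in females. Ttr was at -2.02 in LL versus LD in saline offspring in females. Zic1 was at -0.021 in LL versus LD in poly(I:C) offspring in females. Ak7 was at 0.13, Dynlrb2 at 0.098, Plekhg1 at -0.21 and Synpo2 at -0.13 in poly(I:C) LL versus saline LD in females. Ttr was at 2.39, Kl at 1.07 and Zic1 at -1.60 in the interaction in females. Ttr was at 0.34 in poly(I:C) versus saline over both sexes. Aqp1 was at 0.090 and Sostdc1 at 1.05 in the sex difference in poly(I:C) versus saline under LL. Ttr was at -2.58 in the sex difference in LL versus LD in saline offspring.

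svaseq gave 1 surrogate variable, used as a covariate. This fit called 14 genes for poly(I:C) LD versus saline LL in males and 48 for LL versus LD over both sexes. Ccn2 was at 0.12 in poly(I:C) versus saline under LD in females. Egr2 was at 0.047, Mal at 0.0014, Tdo2 at -0.14, Plk5 at -0.14, Tac1 at 0.27 and Dlx5 at 0.077 in poly(I:C) versus saline under LL in females. Rxrg was at 0.15 in poly(I:C) LD versus saline LL in females. Npnt was at -0.28 in the interaction in females. Lef1 was at -0.14 and Ramp3 at -0.098 in poly(I:C) versus saline under LD in males. Ccdc153 was at 0.42 in the sex difference in poly(I:C) versus saline under LD.

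With the thalamus, striatum and choroid plexus scores as covariates, reversals of those lists were fixed by construction. This fit called 0 genes for LL versus LD in poly(I:C) offspring in males, 0 for poly(I:C) LD versus saline LL in males and 65 for LL versus LD over both sexes. Ccn2 was at 0.50 in poly(I:C) versus saline under LD in females. Ppp1r1b was at 0.12 in poly(I:C) versus saline under LL in females. F5 was at -0.10 and Ttr at -1.16 in LL versus LD in saline offspring in females. Zic1 was at -0.13 in LL versus LD in poly(I:C) offspring in females. Ccdc153 was at 0.92, Ak7 at 1.04, Dynlrb2 at 0.61, Plekhg1 at -0.19, Synpo2 at -0.088 and Dlx5 at 0.0061 in poly(I:C) LL versus saline LD in females. F5 was at 0.018 in poly(I:C) LD versus saline LL in females. Ttr was at 1.184 and Zic1 at -0.81 in the interaction in females. Clic6 was at 0.061 in LL versus LD in poly(I:C) offspring in males. Socs2 was at 0.23, Igfbpl1 at -0.19, Draxin at -0.17 and Dcx at -0.11 in the interaction in males. Prlr was at 0.051, Rsph1 at 0.17, Tekt1 at 0.028, Rarres2 at 0.13 and Dlx6 at 0.11 in poly(I:C) versus saline over both sexes. Ttr was at 0.95 in the interaction over both sexes. Ccdc153 was at 0.037 in the sex difference in poly(I:C) versus saline under LD. Adora2a was at 0.041 in the sex difference in poly(I:C) versus saline under LL. Ttr was at -1.01 in the sex difference in LL versus LD in saline offspring. Synpo2 was at -0.024 in the sex difference in LL versus LD in poly(I:C) offspring. Medians were 0.046 for myelin and -0.0080 for neocortex in poly(I:C) versus saline under LD in females. Medians were -0.020 for endothelial, -0.022 for thalamus and 0.12 for striatum in poly(I:C) versus saline under LL in females. A median was 0.086 for choroid plexus in LL versus LD in saline offspring in females. Medians were 0.078 for CA1 and -0.11 for thalamus in LL versus LD in poly(I:C) offspring in females. Medians were 0.36 for ependymal, -0.16 for thalamus and 0.021 for GABAergic interneuron in poly(I:C) LL versus saline LD in females. A median was 0.027 for striatum in poly(I:C) LD versus saline LL in females. Medians were 0.080 for neurogenesis and -0.10 for respiratory chain in poly(I:C) versus saline under LD in males. A median was -0.0027 for respiratory chain in poly(I:C) LL versus saline LD in males. Medians were 0.11 for CA2 and CA3, -0.16 for neurogenesis and 0.080 for respiratory chain in the interaction in males. Medians were 0.55 for ependymal, 0.013 for thalamus and 0.031 for striatum in poly(I:C) versus saline over both sexes. A median was -0.19 for choroid plexus in the sex difference in poly(I:C) versus saline under LL. A median was 0.20 for choroid plexus in the sex difference in LL versus LD in saline offspring. A median was -0.0058 for choroid plexus in the sex difference in LL versus LD in poly(I:C) offspring.

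Leaving out the 6 libraries with a dentate granule score under -1 left 1 library in female saline LL, where the spread came from other groups. The remaining libraries called 10 genes for LL versus LD in saline offspring in females, 1 for poly(I:C) LL versus saline LD in females, 26 for poly(I:C) LD versus saline LL in females, 0 for LL versus LD in poly(I:C) offspring in males and 0 for poly(I:C) LD versus saline LL in males. It also called 26 for LL versus LD over both sexes and 1 for the sex difference in LL versus LD in saline offspring. Ccn2 was at 0.32 in poly(I:C) versus saline under LD in females. Hlf was at -0.28, Sik1 at 0.0097, Npas4 at 0.016, Egr2 at 0.87, Fgfr3 at -0.017, Ly6c1 at -0.065, Prlr at 0.13, Clic6 at 0.25, F5 at 0.32, Slc17a6 at -1.45, Tcf7l2 at -1.62, Lef1 at -1.68, Myl4 at 0.081, Ppp1r1b at 0.42, Tac1 at 0.64, Dlx1 at 0.74, Dlx5 at 0.73, Gabra4 at -0.60 and Gabrb2 at -0.16 in poly(I:C) versus saline under LL in females. F5 was at -0.44, Ttr at -0.50 and Prlr at -0.77 in LL versus LD in saline offspring in females. Lhfpl3 was at -0.039 and Zic1 at -0.22 in LL versus LD in poly(I:C) offspring in females. Ak7 was at 0.49, Dynlrb2 at 0.23, Plekhg1 at -0.15 and Synpo2 at -0.025 in poly(I:C) LL versus saline LD in females. Slc4a4 was at -0.052, F5 at 0.27, Prlr at 0.64, Rsph1 at 0.13, Ifi27 at 0.22, Tapbp at 0.034 and H2-Eb1 at 0.14 in poly(I:C) LD versus saline LL in females. Prlr was at 0.26, Ttr at 0.88, Kl at 0.16, Sema5b at 0.0021, Tcf7l2 at -0.92, Slc17a6 at -1.40, Zic1 at -1.90, Gabrd at -0.55, Gabrb2 at -0.18 and Gabra4 at -0.59 in the interaction in females. Prlr was at 0.14, Rsph1 at 0.16, Rarres2 at 0.11, Drd1 at 0.016, Dlx1 at 0.052, Dlx5 at 0.043, Dlx6 at 0.20, Gabra4 at -0.045 and Top2a at 0.020 in poly(I:C) versus saline over both sexes. Ttr was at 0.58 in the interaction over both sexes. Ak7 was at 0.97 and Ccdc153 at 1.26 in the sex difference in poly(I:C) versus saline under LD. Npas4 was at 0.45, Slc4a4 at -0.20, Prlr at 0.23, Aqp1 at 0.66, Sostdc1 at 0.67, Tac1 at 0.38 and Adora2a at 0.54 in the sex difference in poly(I:C) versus saline under LL. Prlr was at -0.25 and Ifih1 at -0.12 in the sex difference in LL versus LD in saline offspring. Medians were -0.059 for core clock, 0.11 for immediate early, 0.37 for choroid plexus, -2.08 for thalamus, 0.23 for neocortex, 0.42 for striatum, 0.49 for GABAergic interneuron and 0.036 for GABA receptor in poly(I:C) versus saline under LL in females. Medians were -0.26 for immediate early and -0.39 for choroid plexus in LL versus LD in saline offspring in females. Medians were -0.13 for thalamus, 0.052 for striatum and -0.032 for GABAergic interneuron in poly(I:C) LL versus saline LD in females. Medians were 0.43 for choroid plexus, 0.79 for ependymal, 0.22 for neocortex, 0.37 for striatum, 0.22 for interferon response and 0.24 for antigen presentation in poly(I:C) LD versus saline LL in females. Medians were 0.00039 for core clock, 0.048 for immediate early, 0.48 for choroid plexus, -1.98 for thalamus, -0.047 for GABA receptor and 0.034 for unfolded protein response in the interaction in females. Medians were 0.43 for ependymal, 0.060 for thalamus and 0.065 for GABAergic interneuron in poly(I:C) versus saline over both sexes. A median was 0.13 for choroid plexus in the interaction over both sexes. Medians were 0.77 for ependymal and 0.14 for striatum in the sex difference in poly(I:C) versus saline under LD. Medians were 0.28 for immediate early, 0.86 for choroid plexus and 0.54 for striatum in the sex difference in poly(I:C) versus saline under LL. Medians were -0.070 for immediate early, -0.25 for choroid plexus and -0.33 for interferon response in the sex difference in LL versus LD in saline offspring.

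Leaving out 1 library at a time gave the following ranges, where a value changed sign or a count moved. Counts then ran from 0 to 24 for poly(I:C) versus saline under LL in females, 0 to 1 for LL versus LD in saline offspring in females, 0 to 666 for poly(I:C) LD versus saline LL in females, 0 to 1 for poly(I:C) versus saline under LD in males and 0 to 285 for LL versus LD in poly(I:C) offspring in males. They ran from 0 to 1916 for poly(I:C) LD versus saline LL in males, 0 to 2 for poly(I:C) versus saline over both sexes, 3 to 37 for LL versus LD over both sexes and 0 to 2 for the sex difference in poly(I:C) versus saline under LL. Ccn2 ran from -1.98 to 0.31 in poly(I:C) versus saline under LD in females, turning without Female saline LD replicate 3. The microglia list ran from -0.19 to 0.049 in poly(I:C) versus saline under LD in females, turning without Female saline LD replicate 4. F5 ran from -6.93 to 0.56 and the choroid plexus list from -6.05 to 0.47 in poly(I:C) versus saline under LL in females, turning without Female saline LL replicate 4. Lef1 ran from -0.23 to 2.40 and the thalamus list from -0.54 to 2.83 in poly(I:C) versus saline under LL in females, turning without Female poly(I:C) LL replicate 1. F5 ran from -0.46 to 7.04, Ttr from -1.54 to 8.64, Prlr from -0.33 to 4.71 and the choroid plexus list from -0.40 to 5.80 in LL versus LD in saline offspring in females, turning without Female saline LL replicate 4. Lhfpl3 ran from -0.037 to 1.20 and Zic1 from -0.22 to 2.55 in LL versus LD in poly(I:C) offspring in females, turning without Female poly(I:C) LL replicate 1. Ccdc153 ran from -6.19 to 1.05, Ak7 from -3.65 to 0.90, Dynlrb2 from -3.63 to 0.99 and the ependymal list from -2.47 to 0.55 in poly(I:C) LL versus saline LD in females, turning without Female saline LD replicate 3. The ribosomal protein list ran from -0.087 to 0.00074 in poly(I:C) LL versus saline LD in females, turning without Female poly(I:C) LL replicate 1. F5 ran from -7.29 to 0.18, the choroid plexus list from -6.29 to 0.049 and the interferon response list from -0.42 to 0.062 in poly(I:C) LD versus saline LL in females, turning without Female saline LL replicate 4. Ttr ran from -8.10 to 2.09, Kl from -4.33 to 0.38 and the choroid plexus list from -5.45 to 0.59 in the interaction in females, turning without Female saline LL replicate 4. Slc17a6 ran from -0.15 to 2.66, Zic1 from -0.67 to 2.09 and the thalamus list from -0.73 to 2.66 in the interaction in females, turning without Female poly(I:C) LL replicate 1. Tnnt1 ran from -2.87 to 0.21 in LL versus LD in poly(I:C) offspring in males, turning without Male poly(I:C) LD replicate 3. Prlr ran from -1.30 to 0.059, Ttr from -2.74 to 0.77 and the choroid plexus list from -1.79 to 0.32 in poly(I:C) versus saline over both sexes, turning without Female saline LL replicate 4. The striatum list ran from -3.52 to 0.056 in the sex difference in poly(I:C) versus saline under LD, turning without Female saline LD replicate 3. Aqp1 ran from -5.67 to 0.44, Sostdc1 from -4.21 to 0.95 and the choroid plexus list from -5.58 to 0.99 in the sex difference in poly(I:C) versus saline under LL, turning without Female saline LL replicate 4. Ttr ran from -0.97 to 9.68, the choroid plexus list from -0.15 to 5.84 and the interferon response list from -0.10 to 0.46 in the sex difference in LL versus LD in saline offspring, turning without Female saline LL replicate 4. The respiratory chain list ran from -0.15 to 0.013 in the sex difference in LL versus LD in saline offspring, turning without Male saline LL replicate 4.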

Other observations

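The splits below were fixed as tests before they were run, and the comparison of chromosome 4 genes was chosen after the values were seen.

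Zfp46 and Zbtb40 lie on chromosome 4, at 136284683 to 136293942 and at 136979732 to 137048801, and had opposite signs under LL. Over both sexes LL gave Zfp46 a log2 fold change of 0.39 (adjusted p = 0.0589, edgeR) and Zbtb40 one of -0.48. In males Zfp46 averaged 42.7 CPM in saline LD, 56.4 in saline LL, 30.9 in poly(I:C) LD and 58.0 in poly(I:C) LL, and Zbtb40 17.3, 10.8, 18.0 and 10.4 in the same order. In females they averaged 42.65, 38.1, 42.4 and 55.0, and 15.4, 12.9, 14.6 and 12.6. No test of a link between them was run.

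The libraries of each comparison were regrouped into other splits of the same sizes, counting genes past the threshold where the real comparison had any and genes at an unadjusted p under 0.05 otherwise, the real split included. For 4 of the 21 counts, each taken alone, fewer than 1 in 20 splits gave as many genes, and no allowance was made for the number of counts. In 3 of them no other of the 35 splits reached the real count, which argues against chance in the main fit. Poly(I:C) LD versus saline LL in females gave 3881 genes (highest other 3674), but 1036 with regional covariates and 520 with 1 surrogate variable. Poly(I:C) versus saline under LD in males gave 3883 (highest other 3418), but 915 and 1866 in these fits. Poly(I:C) LD versus saline LL in males gave 96 (highest other 0), but 0 and 14. The sex difference in poly(I:C) versus saline under LD gave 2262 genes, reached by 2 of 50 splits, the highest other at 2318, so chance stays open there. For the others at least 1 in 20 splits gave as many genes, so chance stays open. Poly(I:C) versus saline under LD in females gave 380, reached by 16 of 35 splits, the highest other at 1327. Poly(I:C) versus saline under LL in females gave 1902, reached by 13 of 35 splits, the highest other at 6083. LL versus LD in saline offspring in females gave 1591, reached by 8 of 35 splits, the highest other at 6354. LL versus LD in poly(I:C) offspring in females gave 482, reached by 12 of 35 splits, the highest other at 1127. Poly(I:C) LL versus saline LD in females gave 595, reached by 18 of 35 splits, the highest other at 2281. Poly(I:C) versus saline under LL in males gave 274, reached by 29 of 35 splits, the highest other at 2814. LL versus LD in saline offspring in males gave 1094, reached by 3 of 35 splits, the highest other at 1483. LL versus LD in poly(I:C) offspring in males gave 2, reached by 3 of 35 splits, the highest other at 2169. Poly(I:C) LL versus saline LD in males gave 954, reached by 4 of 35 splits, the highest other at 1297. The interaction in females gave 316 (76 of 100 splits, highest other 2944). The interaction in males gave 856 (32 of 100 splits, highest other 3515). Poly(I:C) versus saline over both sexes gave 1775 (5 of 50 splits, highest other 3595). LL versus LD over both sexes gave 12 (4 of 50 splits, highest other 89). The interaction over both sexes gave 882 (21 of 50 splits, highest other 6447). The sex difference in poly(I:C) versus saline under LL gave 1231 (24 of 50 splits, highest other 4614). The sex difference in LL versus LD in saline offspring gave 1423 (8 of 50 splits, highest other 4368). The sex difference in LL versus LD in poly(I:C) offspring gave 2201 (6 of 50 splits, highest other 4895). Splits that call several times the real count, as in the 2169 genes against 2 for LL in poly(I:C) males and 89 against 12 for LL over both sexes, point to a structure of the samples other than the groups.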
